A study of Homo sapiens with 18 samples.

How the data were processed

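Poly(A) RNA sequencing of 18 human cell culture libraries was analysed as 3 separate comparisons of 3 libraries against 3, each from its own deposited gene table. The groups were SW480-LM3 against SW480-P, LX-2 cells given NID1 vesicles (EV-XP-NID1-LX-2) against LX-2 cells given control vesicles (EV-XP-LX-2), and LV5-NID1 against LV5. The tables share no libraries and differ in unit, so no joint model was fitted. The labels give no batch and do not say whether replicates were separate cultures, so every p-value measures only the spread between these libraries, which may be technical. The letters XP are not explained in the labels.

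The authors name HISAT2 2.1.0 and Bowtie2 2.3.5 among their processing tools without giving either a role. The counting tool, genome build and annotation are not given in the sources used here. In the SW480-LM3 and SW480-P table the deposited unit is a signal that behaves as a read count divided by 1 scaling factor per library: 100% of values were whole multiples of the step of their library within 0.05 read. The recovered reads were 15504205 to 18965163 per SW480-P library and 15531517 to 16586016 per SW480-LM3 library. Signals summed to 1102964 to 1104681 per SW480-P library and 899507 to 908688 per SW480-LM3 library. That table lists 15543 genes, none of them mitochondrially encoded and none under 1 in every library. A second symbol column in it names another symbol than the first for 1596 genes and holds a dash for 1394, and the first column was used. In the other 2 tables the deposited values are TPM, each library summing to 1000000 within rounding, over 31585 and 32555 listed genes, including 805 and 1063 that the authors named as new. The depth behind the TPM values is unknown, so no counting interval is given for them. Replicates correlated on the log2 scale with r from 0.9946 to 0.9959 in the SW480-LM3 table, 0.9893 to 0.9907 in the LX-2 table and 0.9792 to 0.9915 in the LV5 table, across genes, which are not independent replicates. Between replicates of the SW480-LM3 table the chi-square per degree of freedom of the recovered reads was 2.29 to 3.71, over genes with at least 20 reads per pair.

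The following choices were made before the data were examined. Since none of the tables holds counts, the main test was limma 3.58.1 with a variance trend on log2 of the value plus 1, for genes at 1 or more in at least 3 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, each comparison alone and without a replicate block. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The lists cover epithelial, mesenchymal, Wnt target, basement membrane, vesicle biogenesis, matrix protease, cytokine, NF-kB, interferon, cell cycle, hypoxia, cholesterol synthesis, integrated stress response, unfolded protein response, TGF-beta, YAP, p53, mitochondrial and ribosomal protein genes and markers of other cell types, with stellate cell lists for LX-2 and sphingolipid and lysosome lists for LV5. Members were matched by symbol or older symbol, and a set test needs at least 3 measured members. Members that rose or fell were counted over all genes tested and adjusted over the list alone.

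Genes were named by a rule fixed in advance. It takes NID1, the 5 genes with the largest rise and the 5 with the largest fall among called genes with a mean of at least 10 CPM-like signal or 5 TPM in the higher group, a symbol that is not a clone or locus name, and no overlap between groups. It also takes up to 3 called members with the smallest adjusted p from each biological list, and the most abundant member of each technical or marker list. For the overlap of LV5-NID1 with SW480-LM3 it takes 3 genes in each shared direction. Some genes that the rule takes are not reported here.

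Alternatives planned in advance were quantile normalization, pseudocounts of 0.1 and 5, no low filter, a mean of at least 5, no variance trend, an absolute log2 fold change of at least 1, a replicate block, and each library left out in turn with the tested genes kept as with all 6 libraries. Added after the data were seen were library-total scaling and count tests on the recovered reads (edgeR 4.0.16, DESeq2 1.42.0, limma-voom) for the SW480-LM3 table, median-ratio scaling and rescaling without mitochondrial genes for the TPM tables, and removal of trends on GC content and transcript length for all 3. Replicates of unlike groups with the same number were hardly alike (r of -0.047 to 0.063 across genes), so the numbers were not read as pairs. Even so, LV5 and LV5-NID1 replicate 1 matched each other best, as did replicate 3 of the LX-2 groups. On simulated data with known changes of log2 1, limma recovered 100%, 86.6% and 85.1% of changed genes with the libraries of the SW480-LM3, LX-2 and LV5 tables. Few genes were changed in the simulation (67 at this size), so these rates do not carry over to the real calls. Coordinates are from GENCODE 29 on GRCh38. For a gene with no reads in a group, the fold was bounded at 3 reads over the 3 libraries of the group, and intervals from 1 to 3 reads have a level of 95%. These cover counting error only. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.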

Results

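Gene expression was measured by RNA sequencing in 18 libraries from human cell lines, in 6 groups with n = 3 each. SW480 is a colorectal carcinoma line, and SW480-LM3 is described as derived from its parent SW480-P by 3 rounds of selection after injection into the spleen. LX-2 is a hepatic stellate cell line that was incubated for 48 hours with vesicles containing NID1 or with control vesicles. LV5-NID1 is SW480 overexpressing NID1 and exposed for 72 hours to GW4869, an inhibitor of neutral sphingomyelinase that lowers vesicle release, and LV5 is its control. The labels do not say whether LV5 also received GW4869. Recovered reads ranged from 15504205 to 18965163 per SW480-P library and from 15531517 to 16586016 per SW480-LM3 library, and the depth of the other libraries is unknown. Levels are means with SD over 3 libraries, in CPM-like signal for SW480-LM3 and SW480-P and in TPM for the others.

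NID1 (ENSG00000116962) encodes nidogen 1, a glycoprotein that links laminin and collagen IV in basement membranes, and lies on the minus strand of chromosome 1 from 235975830 to 236065162 (GRCh38). It rose in SW480-LM3 from 0.501 ± 0.129 to 46.9 ± 2.21 (SD, n = 3), 93.6-fold. In LX-2 it was 25.4 ± 0.5 TPM with control vesicles and 20.8 ± 2.44 TPM with NID1 vesicles. In LV5-NID1 it rose from 0.02 ± 0.02 to 360 ± 16.6 TPM. The limma log2 fold changes were 4.999 (SE 0.12, adjusted p = 1.3e-14), -0.28 (SE 0.09, adjusted p = 0.0372) and 8.47 (SE 0.06, adjusted p = 8.47e-08). Being fitted on the value plus 1, they are smaller than the ratio of means where the lower group is near 0, and over alternatives they ranged from 3.24 (pseudocount 5) to 6.51 (DESeq2) in SW480-LM3 and from 6.18 (pseudocount 5) to 11.56 (pseudocount 0.1) in LV5-NID1. The LX-2 call was lost without EV-XP-LX-2 replicate 1, 2 or 3 (adjusted p = 0.0895, 0.084 and 0.105), without EV-XP-NID1-LX-2 replicate 1 (0.0532), without a variance trend (0.0511) and with no low filter (0.083), over a range of 0.00785 to 0.105 across alternatives.

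**Figure D1:**
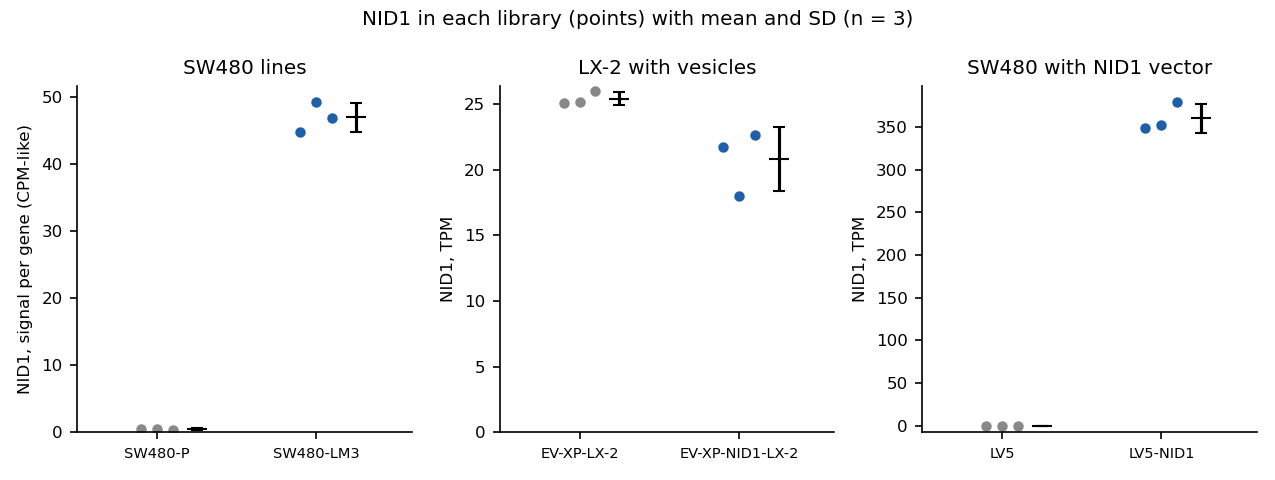
NID1 in each library on linear axes, as CPM-like signal in the SW480 lines and as TPM in LX-2 and in SW480 with the NID1 vector; points are libraries and bars are the mean and SD (n = 3). NID1 was 46.9 in SW480-LM3 against 0.501 in SW480-P, 20.8 against 25.4 TPM in LX-2 and 360 against 0.02 TPM in LV5-NID1.

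The first comparison asks what distinguishes SW480-LM3, selected for spread to the liver, from SW480-P. LCP1, an actin-bundling protein best known from leukocytes, rose from 0.129 ± 0.053 to 520 ± 6.5 (SD, n = 3). MME, the cell surface peptidase neprilysin, rose from 0.097 ± 0.168 to 237 ± 6.65. TFF3, a trefoil peptide of goblet cells, had 0 reads in SW480-P and 160 ± 7.3 in SW480-LM3, at least 2430-fold higher. SPNS2, an exporter of sphingosine 1-phosphate, rose from 1.50 ± 0.291 to 360.5 ± 11.9. GPX2, a glutathione peroxidase of the gut epithelium, rose from 1.46 ± 0.75 to 324 ± 3.62. BASP1, a membrane-bound signalling protein, fell from 603 ± 4.22 to 0 reads, at least 10600-fold lower. CPS1, the first enzyme of the urea cycle, fell from 612.5 ± 20.7 to 0.057 ± 0.0586, which is 10700-fold lower with a counting interval of 3680 to 52200.

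GSTM3, a glutathione transferase, fell from 525 ± 11.7 to 0.285 ± 0.116 in SW480-LM3. LIFR, the receptor of leukemia inhibitory factor, and C4BPB, a chain of the complement regulator C4b-binding protein, each went to 0 reads, at least 5080-fold and 4790-fold lower. In all, 12749 of 14527 genes were called by limma, 6376 higher and 6373 lower, 3479 and 3113 of them by at least 1 on the log2 scale. The libraries of the groups did not overlap in 87.6% of genes, against 10% by chance. Across 14743 genes, which are not independent replicates, SW480-P ranked with LV5 at a Spearman rho of 0.886 and SW480-LM3 with LV5 at 0.694. SW480-LM3 reached 0.713 with LX-2 given control vesicles, so it ranked no closer to LV5 than to another cell line. Change during selection therefore cannot be told apart here from an origin of the SW480-LM3 libraries in another line. With each library divided by its own total, the median of all genes moved to 0.27 and 59.3% of called genes were higher in place of 50%.

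The epithelial list was higher in SW480-LM3, with 19 members up and 1 down of 20 measured (camera adjusted p = 1.75e-06, but adjusted p = 0.383 with an estimated correlation). KRT19, a simple epithelial keratin, rose from 88.1 ± 4.31 to 1789 ± 60.6. VIL1, the microvillar protein villin, rose from 10.1 ± 1.11 to 384 ± 10.5, and the adhesion molecule EPCAM rose from 95.6 ± 1.56 to 412 ± 8.21. Wnt targets were higher, with 15 up and 3 down of 18 (adjusted p = 3e-04, and adjusted p = 0.383 with an estimated correlation). NKD1, NOTUM and AXIN2, which dampen Wnt signalling, rose to 1745 ± 44.9, 365 ± 5.15 and 385 ± 1.48 from 34.8 ± 0.834, 18.2 ± 1.35 and 58.2 ± 1.67. Hypoxia and glycolysis genes were higher, with 19 up and 4 down of 23 (adjusted p = 0.000311, and adjusted p = 0.553 with an estimated correlation). The glucose transporter SLC2A1 rose from 102 ± 7.72 to 1582 ± 69.5, its relative SLC2A3 from 155 ± 5.38 to 716 ± 21.8 and the hexokinase HK2 from 22.2 ± 1.2 to 211 ± 7.48. Integrated stress response genes were higher, with 16 up and 4 down of 21 (adjusted p = 0.0335, adjusted p = 0.581 with an estimated correlation, and adjusted p = 0.0843 after removal of GC and length trends, in a range of 3.33e-05 with fry to 0.581). TRIB3, a pseudokinase induced by ATF4, rose from 26.9 ± 0.0581 to 124 ± 7.94. All 30 ribosomal protein genes fell, RPS2 from 6457 ± 283 to 2742 ± 43.5 (adjusted p = 1.33e-11, and adjusted p = 0.486 with an estimated correlation), but with quantile normalization 26 fell and 2 rose.

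The other 16 lists tested in SW480-LM3 were not called (adjusted p = 0.128 to 0.91). Of 21 mesenchymal genes 9 rose and 11 fell: the matrix protein TNC rose from 2.14 ± 0.648 to 254 ± 4.94, while the ligand WNT5A fell from 100.2 ± 4.26 to 0 reads and the hyaluronan receptor CD44 from 205 ± 1.99 to 19.9 ± 2.9. Basement membrane genes were 10 up and 10 down of 20, with COL18A1 up from 9.84 ± 0.771 to 254 ± 7.35. Of 20 YAP targets 4 rose and 14 fell (adjusted p = 0.128, and 0.0496 with library-total scaling, in a range of 4.01e-07 with fry to 0.486), with CYR61, a secreted matricellular protein, down from 145 ± 3.91 to 2.51 ± 0.816. Among 22 vesicle biogenesis genes 8 rose and 11 fell, with RAB27B, a Rab GTPase of vesicle secretion, down from 28.8 ± 1.53 to 0.0197 ± 0.0341. Matrix proteases were 7 up and 9 down of 17, with cathepsin L (CTSL) down from 223 ± 12 to 4.07 ± 0.975. Cytokines were 7 up and 2 down of 11, with the chemokine CCL20 up from 1.54 ± 0.78 to 23.4 ± 1.13. Interferon genes were 12 up and 5 down of 19, with BST2, which tethers enveloped virus particles, down from 270 ± 14.5 to 1.81 ± 0.376. Cell cycle genes were 12 up and 15 down of 28, with MKI67 up from 275 ± 7.11 to 692 ± 2.98. Unfolded protein response genes were 8 up and 10 down of 18.

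Some lists in SW480-LM3 differed in sign between summaries. For NF-kB targets, 6 up and 7 down of 14, the median log2 change was -0.038, the mean 0.18 and camera pointed up. For cholesterol synthesis, 9 up and 14 down of 23, these were -0.41, 0.033 and down. For TGF-beta targets, 9 up and 9 down of 19, they were 0.11, -0.34 and up, with IGFBP3 down from 174 ± 2.57 to 6.96 ± 0.392. For p53 targets, 10 up and 7 down of 18, camera pointed up and fry down. Hepatocyte markers were 4 up of 4, leukocyte markers 2 up of 3 with CD68 lower (adjusted p = 0.0084, but 0.867 with library-total scaling, in a range of 3.13e-05 to 0.867), stromal markers 2 up of 3, and the single endothelial marker, ESAM, fell from 32.2 ± 1.39 to 0.206 ± 0.108. Counts adjusted over the list alone were the same for every list in this comparison.

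**Figure D2:**
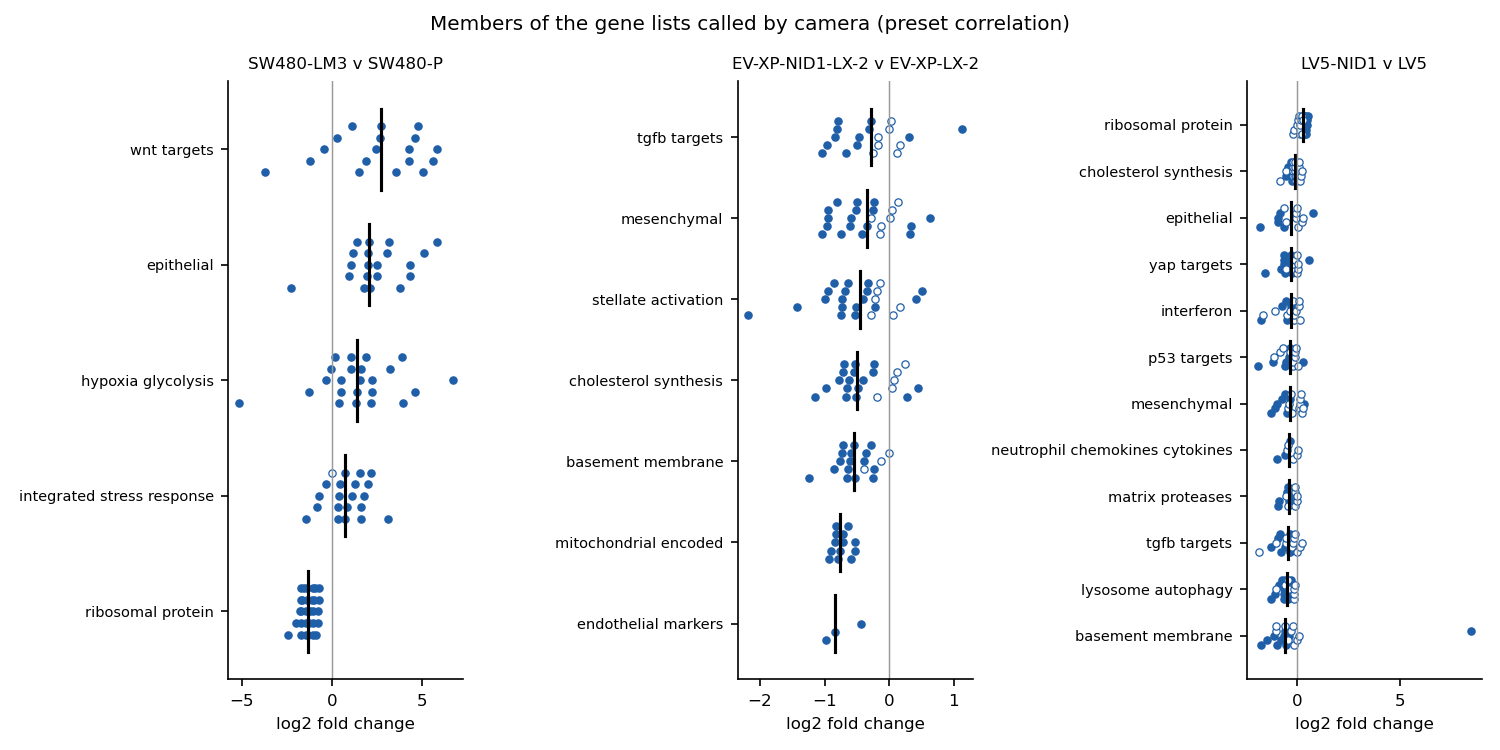
Log2 fold change of each measured member of the lists that camera called with the preset correlation, 1 panel per comparison; filled points passed limma over all genes, open points did not, and black bars are list medians. All 30 ribosomal protein genes lie below 0 in SW480-LM3, where quantile normalization left 26 lower, and the far right point of the LV5-NID1 panel is NID1 at 8.47.

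The next comparison asks how vesicles containing NID1 affect LX-2 stellate cells. HMOX1, heme oxygenase 1, rose with NID1 vesicles from 39.0 ± 0.776 to 123 ± 4.53 TPM (SD, n = 3), and TNFRSF10D, a decoy receptor for TRAIL, rose from 21.7 ± 0.594 to 76.1 ± 2.61 TPM. MIR210HG, the host transcript of the hypoxia-induced microRNA miR-210, fell from 12.9 ± 0.777 to 0.823 ± 0.136 TPM. COL6A3, a collagen VI chain, fell from 12.8 ± 1.24 to 2.06 ± 0.386 TPM. KRT81, a hair keratin, fell from 21.5 ± 1.52 to 4.02 ± 0.712 TPM, and MEGF6 fell from 30.3 ± 1.17 to 8.22 ± 1.06 TPM. C19orf33 fell from 7.16 ± 2.4 to 1.27 ± 0.644 TPM. The readthrough transcripts INO80B-WBP1 and RNASEK-C17orf49 rose to 9.66 ± 1.6 and 11.6 ± 1.61 TPM from 2.47 ± 0.373 and 3.66 ± 1.44 TPM.

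In LX-2, limma called 6687 of 15802 genes, 2805 higher and 3882 lower with NID1 vesicles, but only 88 and 192 of them by at least 1 on the log2 scale. The share of called genes that were higher, 41.9%, was 51.1% with quantile normalization, 51.3% with median-ratio scaling, 50.6% without GC and length trends and 36.1% without mitochondrial genes. Groups did not overlap in 55.9% of genes, against 10% by chance. HIST2H2AA4, 1 of a pair of near-identical histone H2A genes, was 23.8 ± 6.32 against 4.58 ± 4.07 TPM (adjusted p = 0.0283), a call lost without EV-XP-NID1-LX-2 replicate 2 or 3 (adjusted p = 0.083 and 0.0733), with no low filter (0.0919) and with a pseudocount of 0.1 (0.0859), in a range of 0.00519 to 0.0919.

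Mitochondrially encoded mRNAs held 6.06 ± 0.11% of TPM with control vesicles and 3.66 ± 0.132% with NID1 vesicles, and all 13 fell (camera adjusted p = 6.68e-08, and adjusted p = 0.656 with an estimated correlation). The stellate activation list was lower, with 16 members down and 2 up of 24 (adjusted p = 0.000501, and adjusted p = 0.972 with an estimated correlation). COL6A2 fell from 112 ± 2.3 to 56.3 ± 7.14 TPM and COL5A2, a fibrillar collagen chain, fell from 119 ± 3.29 to 71.2 ± 6.11 TPM. None of 19 basement membrane genes rose and 16 fell (adjusted p = 1.64e-05, and adjusted p = 0.677 with an estimated correlation). COL18A1, COL4A1 and the laminin chain LAMC1 fell from 40.5 ± 1.77, 67.7 ± 3.03 and 143 ± 4.06 to 16.8 ± 2.32, 44.4 ± 0.523 and 86.3 ± 8.23 TPM. Mesenchymal genes were lower, with 14 down and 3 up of 23 (adjusted p = 0.0117, and adjusted p = 0.972 with an estimated correlation). TGFBI, a matrix protein induced by TGF-beta, fell from 794 ± 25.8 to 385 ± 34.2 TPM. Cholesterol synthesis genes were lower, with 15 down and 2 up of 22, or 16 and 3 adjusted over the list alone (adjusted p = 0.00142, and adjusted p = 0.677 with an estimated correlation). FDFT1, squalene synthase, fell from 62.4 ± 2.57 to 37.5 ± 2.09 TPM.

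TGF-beta targets in LX-2 were 10 down and 2 up of 19, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.049, and adjusted p = 0.972 with an estimated correlation). KLF10, an early TGF-beta response gene, went the other way, from 115 ± 5.71 to 251 ± 6.61 TPM. This call was lost without EV-XP-LX-2 replicate 3 (0.0532) or EV-XP-NID1-LX-2 replicate 1 (0.0553), at a mean of at least 5 (0.134), with a pseudocount of 0.1 (0.0502), without GC and length trends (0.0943) and without mitochondrial genes (0.051), in a range of 0.00824 to 0.972. All 3 endothelial markers measured fell, among them ROBO4 from 36.3 ± 0.637 to 26.5 ± 2.68 TPM (adjusted p = 0.0284, adjusted p = 0.677 with an estimated correlation and 0.34 with no low filter, in a range of 0.00388 with fry to 0.677).

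**Figure D3:**
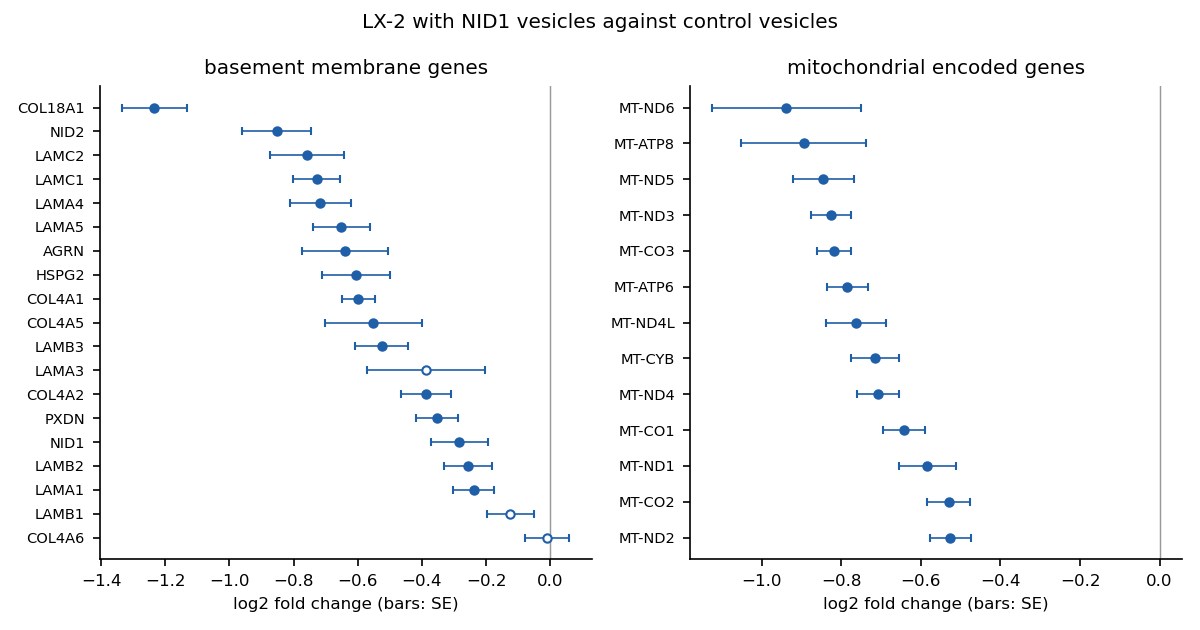
Log2 fold change with SE (n = 3 per group) of the 19 basement membrane genes and 13 mitochondrially encoded mRNAs measured in LX-2, NID1 vesicles against control vesicles; filled points passed limma over all genes and open points did not. Of the basement membrane genes 16 fell, and all 13 mitochondrial mRNAs fell, against 12 with quantile normalization.

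The other 14 lists tested in LX-2 were not called by camera (adjusted p = 0.0544 to 0.912). Hypoxia genes were 11 down and 2 up of 21, or 12 and 2 adjusted over the list alone (adjusted p = 0.0544, in a range of 0.00864 to 0.972), with the aldolase ALDOC down from 25.1 ± 3.65 to 6.88 ± 0.604 TPM and the vasodilator peptide gene ADM up from 58.2 ± 1.79 to 102 ± 4.99 TPM. Camera called the hypoxia list without EV-XP-LX-2 replicate 1 or 2 (0.0463 and 0.0211), without EV-XP-NID1-LX-2 replicate 1 (0.0498), with quantile normalization (0.0252), with a replicate block (0.0471) and with no low filter (0.00864). Interferon genes were 9 down and 1 up of 21 (adjusted p = 0.0665), and were called without EV-XP-LX-2 replicate 2 (0.0482) and with no low filter (0.00824), in a range of 0.00388 with fry to 0.677. Matrix proteases were 10 down and 4 up of 19, with tissue plasminogen activator (PLAT) down from 145 ± 9.04 to 63.5 ± 5.38 TPM and MMP3 up from 7.82 ± 0.869 to 15.4 ± 0.761 TPM. Quiescence genes were 2 up and 1 down of 7. Among cytokines, 3 up and 5 down of 17, the monocyte attractant CCL2 fell from 44.4 ± 2.2 to 20.1 ± 0.716 TPM and IL11 rose from 91.2 ± 6.84 to 208 ± 24.6 TPM. For cytokines the list median was 0.026, the mean -0.01, and camera pointed up and fry down. Vesicle biogenesis genes were 8 up and 4 down of 20, with the tetraspanin CD63 up from 801 ± 35.8 to 1150 ± 81.4 TPM, and their median was -0.001 where the mean was 0.037 and camera pointed up. Cell cycle genes were 10 up and 7 down of 28, or 11 and 9 adjusted over the list alone, with a median of -0.047, a mean of 0.027 and camera up. Unfolded protein response genes were 4 up and 3 down of 18, with a median of -0.016, a mean of 0.001 and camera up. NF-kB targets were 4 up and 3 down of 14, and the integrated stress response 3 up and 9 down of 21. YAP targets were 5 up and 8 down of 20 and p53 targets 4 up and 5 down of 18. Ribosomal protein genes were 2 up and 9 down of 30 (adjusted p = 0.187, and 0.00581 without EV-XP-NID1-LX-2 replicate 2, in a range of 0.00581 to 0.972). RPS23 was 3071 ± 483 against 3425 ± 44.4 TPM (adjusted p = 0.226), and was called without that library (0.00144) and with quantile normalization (0.0356). Of 3 leukocyte markers 1 fell, CD68, from 43.7 ± 1.99 to 18.6 ± 2.69 TPM, as did the only hepatocyte marker measured, SERPINA1, from 21.0 ± 0.652 to 13.3 ± 0.488 TPM. For the other lists, counts adjusted over the list alone were the same.

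The remaining comparison concerns the vesicle pathway and epithelial to mesenchymal transition in SW480 cells overexpressing NID1. TXNIP, which binds thioredoxin and limits glucose uptake, rose in LV5-NID1 from 16.7 ± 0.541 to 47.5 ± 1.9 TPM (SD, n = 3). GAS5, a noncoding host of small nucleolar RNAs, rose from 1172 ± 44 to 2559 ± 159 TPM. CLGN, a chaperone of the endoplasmic reticulum, rose from 6.89 ± 0.831 to 18.3 ± 1.49 TPM, and CSTA, an inhibitor of cysteine proteases, rose from 1.80 ± 0.0764 to 7.15 ± 1.31 TPM. CLU, the secreted chaperone clusterin, fell from 663 ± 30.7 to 161 ± 7.02 TPM. ALPP, placental alkaline phosphatase, fell from 261 ± 12 to 45.5 ± 13.8 TPM, and PSG5, a pregnancy-specific glycoprotein, fell from 9.91 ± 0.881 to 0.757 ± 0.391 TPM. UPK3B, a uroplakin, was 1.15 ± 0.872 against 7.32 ± 1.31 TPM (adjusted p = 0.0167), a call lost without LV5 replicate 1, 2 or 3 (adjusted p = 0.0677, 0.0705 and 0.0503) and with a pseudocount of 0.1 (0.0516), in a range of 0.00108 to 0.0705.

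In LV5-NID1, limma called 2572 of 15508 genes, 1127 higher and 1445 lower, of which 22 and 198 differed by at least 1 on the log2 scale. Groups did not overlap in 43.3% of genes, against 10% by chance. Called genes numbered 713, 714 and 1045 without LV5 replicate 1, 2 and 3, 1675 and 750 without LV5-NID1 replicate 1 and 2, 3325 without LV5-NID1 replicate 3, 1532 with no low filter and 890 with a replicate block. With quantile normalization 54.7% of called genes were higher in place of 43.8%. The share was 25.9% to 39.1% with 1 library left out, 34% with no low filter and 26.2% with a replicate block. Because LV5-NID1 differs from LV5 in NID1 and, as far as the labels state, in GW4869, the 2 cannot be told apart here.

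The lysosome and autophagy list was lower in LV5-NID1 and was the 1 call of this comparison kept with an estimated correlation (camera adjusted p = 4.77e-13, and adjusted p = 0.0233 with an estimated correlation). Of 24 members 16 fell, or 20 adjusted over the list alone, and none rose. GABARAPL1, an autophagosome protein, fell from 132 ± 3.24 to 60.5 ± 0.84 TPM, the cholesterol carrier NPC2 from 234 ± 6.45 to 126 ± 3.85 TPM and the saposin precursor PSAP from 674 ± 18.4 to 435 ± 11.2 TPM. Members that fell numbered 10 without LV5 replicate 1 or 2 and 19 without LV5-NID1 replicate 3, which stood apart from the other 2.

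Basement membrane genes in LV5-NID1 were lower, with 9 down of 19 and NID1, which was not left out of the test, up, or 12 down adjusted over the list alone (adjusted p = 0.000291, and adjusted p = 0.103 with an estimated correlation), although fry pointed up (median log2 change -0.58, mean -0.19). LAMA1, a laminin chain, fell from 25.3 ± 1.36 to 10.9 ± 1.23 TPM, and NID2, the relative of NID1, fell from 10.1 ± 1.52 to 3.04 ± 0.306 TPM. Of 13 matrix proteases 6 fell, or 7 adjusted over the list alone (adjusted p = 0.000237, and adjusted p = 0.103 with an estimated correlation), with CTSL from 222 ± 6.49 to 118 ± 3.56 TPM. Of 18 TGF-beta targets 7 fell, or 10 with 1 up adjusted over the list alone (adjusted p = 9.48e-05, and adjusted p = 0.0824 with an estimated correlation). Of 19 YAP targets 10 fell and 1 rose, or 11 and 1 adjusted over the list alone (adjusted p = 5.55e-05, and adjusted p = 0.152 with an estimated correlation). Among them CCN1, given above under its older symbol CYR61 for SW480-LM3, fell from 86.1 ± 0.862 to 54.4 ± 2.42 TPM. Of 17 p53 targets 6 fell and 1 rose, or 8 and 1 adjusted over the list alone (adjusted p = 0.000714, and adjusted p = 0.103 with an estimated correlation), with the cell cycle inhibitor CDKN1A from 76.4 ± 3.57 to 33.1 ± 1.97 TPM. Of 16 interferon genes 5 fell (adjusted p = 0.00169, and adjusted p = 0.103 with an estimated correlation), with IFI6 from 16.1 ± 1.39 to 4.03 ± 1.08 TPM. Of 8 cytokines 3 fell, or 5 adjusted over the list alone (adjusted p = 0.00597, and adjusted p = 0.103 with an estimated correlation), with IL6 from 3.75 ± 0.456 to 1.39 ± 0.0929 TPM.

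The epithelial and mesenchymal lists in LV5-NID1 were both lower. Of 14 epithelial genes 5 fell and 1 rose, with KRT8 from 780 ± 17.2 to 411 ± 32.3 TPM (camera adjusted p = 0.0369, and adjusted p = 0.152 with an estimated correlation). That call was lost without LV5-NID1 replicate 1 or 2 (0.0556 and 0.0555), at a mean of at least 5 (0.104) and without GC and length trends (0.0544), in a range of 0.00025 with fry to 0.152. Of 18 mesenchymal genes 7 fell and 1 rose, or 10 and 3 adjusted over the list alone, with S100A4 from 1240 ± 71.6 to 621 ± 30.4 TPM (adjusted p = 0.0348, and adjusted p = 0.25 with an estimated correlation). It was lost without LV5-NID1 replicate 1 (0.057) and at a mean of at least 5 (0.0779), in a range of 0.000598 with fry to 0.25. Of 23 cholesterol synthesis genes 4 fell, with SC5D from 66.8 ± 2.63 to 45.0 ± 3.49 TPM (adjusted p = 0.0227, and adjusted p = 0.354 with an estimated correlation), a call lost without LV5-NID1 replicate 1 (0.0689) and with quantile normalization (0.159), in a range of 0.00276 to 0.354. Of 30 ribosomal protein genes 18 rose, or 21 adjusted over the list alone (adjusted p = 1.57e-08, and adjusted p = 0.0824 with an estimated correlation), against 5 with quantile normalization (0.162) and 4 with no low filter. They numbered 5, 3 and 6 without LV5 replicate 1, 2 and 3, 8 without LV5-NID1 replicate 2 and 24 without LV5-NID1 replicate 3. RPS23 rose from 4337 ± 180 to 5788 ± 407 TPM (adjusted p = 0.0137), a call lost without LV5 replicate 2 or 3 (0.0629 and 0.0548), with no low filter (0.0752) and with quantile normalization (0.336), in a range of 0.0068 to 0.336.

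Counts of members that fell in LV5-NID1 also changed over 1.5 times with LV5 replicate 1, 2 or 3 or LV5-NID1 replicate 1, 2 or 3 left out. They ranged from 4 to 10 for basement membrane genes, 4 to 12 for TGF-beta targets, 5 to 11 for YAP targets, 2 to 10 for p53 targets, 2 to 7 for interferon genes, 1 to 4 for cytokines, 3 to 8 for mesenchymal genes and 2 to 8 for cholesterol synthesis genes, while camera called 9 of the 12 lists without each library.

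The other 10 lists tested in LV5-NID1 were not called (adjusted p = 0.0594 to 0.736), though several were under alternatives. Of 21 vesicle biogenesis genes 3 fell (adjusted p = 0.0832), among them CD63 from 453 ± 22.4 to 327 ± 16 TPM, and the list was called without LV5-NID1 replicate 3 (0.0285), with no low filter (0.0188) and without GC and length trends (0.0275), in a range of 0.00332 with fry to 0.247. Sphingolipid genes were 1 up and 3 down of 21, or 2 and 4 adjusted over the list alone (adjusted p = 0.461), with SMPD1, the acid sphingomyelinase of lysosomes, down from 23.3 ± 1.59 to 11.0 ± 1.39 TPM. Of 8 Wnt targets 3 fell, among them the Wnt antagonist DKK1 from 88.7 ± 1.17 to 60.6 ± 5.26 TPM (adjusted p = 0.13, and 0.00198 with no low filter, in a range of 0.00198 to 0.883). Unfolded protein response genes were 1 up and 5 down of 18, or 1 and 6 adjusted over the list alone, with calreticulin (CALR) down from 391 ± 13.2 to 263 ± 6.92 TPM (adjusted p = 0.0594). That list was called without LV5-NID1 replicate 3 (0.004), with no low filter (0.0126), without GC and length trends (0.0137) and without mitochondrial genes (0.043), in a range of 0.004 to 0.393. Hypoxia genes were 3 up and 6 down of 21, or 6 and 8 adjusted over the list alone, and integrated stress response genes 0 up and 3 down of 21, or 4 and 9. NF-kB targets were 2 down of 13 (adjusted p = 0.13, but 0.0472 without LV5 replicate 3 and 0.0455 with no low filter, in a range of 0.0455 to 0.456). Cell cycle genes were 3 up and 2 down of 28, or 4 and 4 adjusted over the list alone. None of 13 mitochondrial mRNAs was called (adjusted p = 0.0868 for the list, but 0.0141 without LV5 replicate 2, 0.0427 with quantile normalization and 0.036 without GC and length trends, in a range of 0.0141 to 0.535), with MT-ATP8 at 22960 ± 2520 against 26210 ± 3780 TPM. Of 2 leukocyte markers 1 fell, CD68, from 3.64 ± 0.588 to 1.35 ± 0.268 TPM, a call lost with a replicate block (adjusted p = 0.0501). The single endothelial marker measured, ESAM, was 40.0 ± 6.47 against 62.2 ± 2.37 TPM (adjusted p = 0.022), a call lost without LV5 replicate 1, 2 or 3 (0.0742, 0.086 and 0.073), without LV5-NID1 replicate 2 (0.0648), with no low filter (0.0503) and with a replicate block (0.0561), in a range of 0.00379 to 0.086. Of 3 stromal markers none was called over all genes and 1 was lower adjusted over the list alone, and the list was called with no low filter (0.0211), in a range of 0.0211 to 0.393. No hepatocyte marker was measured. For lists with no second count given, counts adjusted over the list alone were the same.

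NID1 was higher in both LV5-NID1 and SW480-LM3, and the calls of these comparisons were set side by side. Of 12428 genes tested in both, 1977 were called in both, 1079 in the same direction and 898 in opposite directions. In SW480-LM3 4941 of the 12428 were called higher and 5948 lower, so most LV5-NID1 calls would overlap in any case. Genes lower in both numbered 745, where independent lists would share 593.5, and genes higher in both numbered 334 against 376.1. Genes higher in SW480-LM3 and lower in LV5-NID1 numbered 402 against 493, and the reverse 496 against 452.8. Besides NID1, H6PD, which feeds NADPH to the endoplasmic reticulum, rose in SW480-LM3 from 7.30 ± 0.653 to 159 ± 9.36, and in LV5-NID1 was 5.33 ± 0.492 against 3.93 ± 0.18 TPM (adjusted p = 0.0451). This LV5-NID1 call was lost without LV5 replicate 1, 2 or 3 (0.109, 0.127 and 0.122), without LV5-NID1 replicate 1 or 2 (0.102 and 0.145), with no low filter (0.106), with a replicate block (0.0988) and without mitochondrial genes (0.0546), in a range of 0.0133 to 0.145. PFKFB4, a regulator of glycolysis, rose in LV5-NID1 from 10.1 ± 0.425 to 14.5 ± 0.442 TPM and in SW480-LM3 from 5.24 ± 0.472 to 90.1 ± 7.65. CPS1, GSTM3 and BASP1 were lower in both, and in LV5-NID1 the first pair fell from 336 ± 9.54 and 480 ± 29.1 to 229 ± 14.8 and 254 ± 23.1 TPM. Genes were ranked here by summed absolute log2 fold change, which SW480-LM3 dominates. The changes of these genes were -9.182, -8.682 and -9.239 there and -0.555, -0.916 and -0.342 in LV5-NID1. They are also among the 58 genes at 50 or more in SW480-P and under 1 in SW480-LM3. BASP1 was 270 ± 21 against 342.5 ± 16.9 TPM in LV5-NID1 (adjusted p = 0.0282), a call lost without LV5 replicate 1, 2 or 3 (0.0971, 0.0893 and 0.0717), without LV5-NID1 replicate 2 (0.0937), with no low filter (0.0611) and with quantile normalization (0.0513), in a range of 0.015 to 0.0971. Across the genes tested in both, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.075 and a Spearman rho of 0.019. Against 1079 with all libraries, genes called in the same direction numbered 357, 352 and 477 without LV5 replicate 1, 2 and 3, and 716 and 355 without LV5-NID1 replicate 1 and 2, 679 with no low filter and 415 with a replicate block.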

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

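Library-total and median-ratio scaling, rescaling without mitochondrial genes, removal of GC and length trends and the count tests on recovered reads were chosen after the data were seen. The other alternatives were planned. Among the main results, 104 values under alternatives stayed within 1.5 times the reported count or on the same side of the threshold, 18 counts moved further and 6 calls were lost. Among gene lists tested with camera 995 stayed, including lists called in neither fit, 24 gained a call and 40 lost one. With an estimated correlation, 0 of 5 called lists stayed called in SW480-LM3, 0 of 7 in LX-2 and 1 of 12 in LV5-NID1. Of the lists lost in LV5-NID1, the epithelial, TGF-beta, interferon and cytokine lists had estimates of -0.045, -0.005, -0.019 and -0.046. These lie below the preset 0.01, so a higher correlation did not end those calls, and what did was not tested. The other lost lists had estimates above 0.01. Fry, which compares a list with no change and not with other genes, gave the same call 41 times, called 22 more and reversed 1. Among named genes 3351 stayed, 206 lost their call and 2 gained one. Requiring an absolute log2 fold change of at least 1, a stricter test by construction, left 6592 genes in SW480-LM3, 280 in LX-2, 220 in LV5-NID1 and 81 called in the same direction in both SW480 comparisons. With no low filter, which tests more genes, LV5-NID1 gave 1532 calls and 679 in the same direction as SW480-LM3. With a replicate block it gave 890 and 415, and the labels do not say whether the replicate numbers pair the libraries. Such a block also leaves fewer residual degrees of freedom. With 1 library left out, LV5-NID1 gave 713 to 3325 calls and 352 to 1442 in the same direction as SW480-LM3, against 2572 and 1079, while LX-2 gave 4762 to 7132 and SW480-LM3 12485 to 12563. NID1 in LX-2 was not called without a variance trend (log2 fold change -0.283, adjusted p = 0.0511) or with no low filter (-0.283, 0.083), and ranged from -0.345 to -0.188 with 1 library left out, where 4 of 6 fits lost the call. Over basement membrane genes in LV5-NID1, a list that holds NID1 itself (log2 fold change 8.466), fry pointed up where the mean was -0.193. The cause was not tested for NID1 in LX-2, for this list or for the replicate block. Tests on recovered reads called 12940 (DESeq2) to 13135 (limma-voom) genes in SW480-LM3. Count tests had been planned only for tables that hold counts, and their use on recovered reads was decided after the data were seen. They were not run on the TPM tables, whose depth is unknown. On simulated data limma recovered 70.1%, 62.7% and 46.3% of changes of log2 0.5 with the libraries of SW480-LM3, LX-2 and LV5. Of the simulated calls 1.49%, 5.29% and 10% were false, the last 2 above the 5% that the threshold allows. Each table was simulated in a single draw, with 66 or 67 genes changed at each size. In the real data 87.8%, 42.3% and 16.6% of genes were called, so these rates do not carry over to the real calls. Only SW480-LM3 was simulated as counts with a common dispersion, so the rates are not compared between tables.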

Other observations

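The gene families below and the tests in this part were chosen after the results were seen, except the splits of the libraries, although quantile normalization and the leaving out of libraries were planned as settings. Families were taken by the letters that open their symbols, with at least 10 members measured. In LX-2 all 10 pregnancy-specific glycoprotein genes (PSG) measured fell with NID1 vesicles (median log2 change -0.73, camera adjusted p = 0.000966 over 167 families, and adjusted p = 0.717 with an estimated correlation). With quantile normalization or median-ratio scaling 9 of the 10 fell. PSG4 fell from 76.2 ± 1.55 to 49.99 ± 0.581 TPM (SD, n = 3). Histone genes went the other way, with 22 of 36 up and none down (adjusted p = 1.97e-08, and adjusted p = 0.696 with an estimated correlation). HIST1H1C, a linker histone, rose from 44.0 ± 2.3 to 108 ± 7.66 TPM, and HIST1H2BK, an H2B histone, rose from 49.3 ± 3.59 to 109 ± 4.85 TPM. In LV5-NID1, 9 of 39 histone genes fell and none rose (adjusted p = 1.36e-05, and adjusted p = 0.842 with an estimated correlation). In SW480-LM3 the histone median was -1.473. There 21 of 24 fell with quantile normalization or library-total scaling, and 22 with GC and length trends removed. Whether the comparisons differ was not tested. The libraries hold poly(A) RNA, and how fully such libraries capture histone transcripts was not tested either. Of 19 keratin genes, pseudogenes and an antisense gene included, 8 fell in LV5-NID1 and none rose (adjusted p = 6.12e-05, and adjusted p = 0.842 with an estimated correlation), KRT17 from 194 ± 8.19 to 70.8 ± 5.14 TPM.

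In SW480-LM3 all 11 NDUFB genes, subunits of respiratory complex I, fell (median log2 change -1.34, adjusted p = 0.00185 over 170 families, and adjusted p = 0.545 with an estimated correlation). NDUFB10 fell from 243 ± 14.7 to 50.8 ± 1.11, and 10 of the 11 fell with GC and length trends removed (median -1.04). All 10 PSMB genes, beta subunits of the proteasome, fell as well (median -1.45, adjusted p = 0.00232, and adjusted p = 0.528 with an estimated correlation), PSMB5 from 266 ± 13.3 to 98.4 ± 3.39, and 9 fell with library-total scaling. These were not the only families that camera called in SW480-LM3. Medians were also lower for RPL (-1.275), MRPL (-1.242), COX (-1.375) and TIMM (-1.026), among others. They were higher for ARHGAP, ARHGEF, IRF, KDM and SOX. Medians of the families named here kept their sign under each scaling tried. Median log2 changes also differed between chromosomes. In SW480-LM3 the SD of the medians of 22 autosomes was 0.3, above the highest of 1000 permutations of genes at 0.135 (permutation p = 0.001, the smallest they can give), and 0.206 against 0.112 after removal of GC and length trends. It was smaller but also above the permutations in LV5-NID1 (0.049 against 0.026, and 0.025 against 0.023 after the removal) and, before the removal, in LX-2 (0.034 against 0.029, then 0.022 against 0.03, permutation p = 0.1). The permutations treat genes as independent, so their p-values do not measure the spread between libraries. In SW480-LM3 the highest medians were 0.56 on chromosome 22 and 0.48 on chromosome 16 and the lowest -0.48 on chromosome 5, and after that removal the highest was 0.3 on chromosome 16 and the lowest -0.41 on chromosome 9.

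The number of genes that differ between SW480-LM3 and SW480-P is the first pattern. Dividing each library by its own total left 12744 genes called, which argues against the authors' scaling as the whole cause. All 58 genes at 50 or more in SW480-P and under 1 in SW480-LM3 were at 5 TPM or more in each LV5 library. This argues against a mixture holding cells like SW480-P or LV5, which would bring these transcripts. It cannot test a mixture of other cells with SW480 cells that lost these transcripts. SW480-LM3 ranked with LV5, an SW480 derivative, at a rho of 0.694 (library pairs 0.686 to 0.7), below its 0.713 with LX-2 (0.71 to 0.715), where SW480-P reached 0.886, and with SW480-P itself, in the same table, at 0.793 (0.787 to 0.798), where SW480-P with LX-2 reached 0.794, so SW480-LM3 libraries from a line other than SW480 may be one source of the difference. Change during selection stays open and untested, and genotypes, not used here, would be needed to decide.

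The second pattern is the lower basement membrane, stellate activation and mitochondrial genes in LX-2 with NID1 vesicles. With an estimated correlation camera called none of these lists (adjusted p = 0.677, 0.972 and 0.656). The basement membrane median was -0.426 after removal of GC and length trends and -0.494 with median-ratio scaling, against -0.55 before. At the preset correlation the basement membrane and stellate activation lists stayed called and lower with that removal, median-ratio scaling and quantile normalization. The removal and quantile normalization argue against GC and length or scaling as the whole cause. Median-ratio scaling could hardly end such a call. It moved genes nearly alike (median of all genes from -0.048 to 0.008), and camera sets a list against the other genes. With the same removal 13 mitochondrial mRNAs fell, and at least 12 fell under median-ratio scaling and quantile normalization. An effect of NID1 in the vesicles may account for these changes, but other differences between the vesicle preparations and a batch that follows the groups stay open and untested.

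The third pattern is the lower lysosome list and the higher ribosomal protein genes in LV5-NID1. The lysosome median of -0.50 became -0.454 after removal of GC and length trends, -0.397 with quantile normalization and -0.469 without LV5-NID1 replicate 3, which argues against each as the whole cause. The ribosomal protein median of 0.29 was 0.286 and 0.275 with the same removal and without that library, but 0.088 with quantile normalization, where the smaller change ended the call, and 0.28 with median-ratio scaling, so scaling of the TPM values cannot be told apart from a change of these genes. Overexpression of NID1 and GW4869 may each contribute, and this design cannot separate them.

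The 6 libraries of a comparison can be split into groups of 3 in 10 ways, which are too few for a share under 0.05. The real split called 12749 genes in SW480-LM3, 6687 in LX-2 and 2572 in LV5-NID1 with limma, and 1 of the 10 splits, the real one, called as many in each. The highest of the other splits called 0, 3 and 3 genes. Each of them mixes libraries of both real groups, which widens the spread within a group. Few calls in them were therefore fixed by the design and are no measure of chance.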
